A study of Mus musculus with 2 samples.

How the data were processed

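Viable, tdTomato-positive cells sorted from the median eminence and arcuate nucleus of 10-day-old CD-1 mice were profiled by droplet single-cell RNA sequencing. The reporter was switched on by Cre driven from the Ins2 promoter. There were 2 libraries, 1 from control animals and 1 from animals heterozygous for both Irx3 and Irx5 (dHet), each made from 1 pool of 5 mice per the labels. Per the labels' protocols, tissue was digested with papain, cells that took up a viability dye were excluded in the sorter, and 3′ v3 chemistry of the 10x Genomics Chromium system was used. Alignment and counting were done by the authors with Cell Ranger and genome build mm10, per the submitters' processing notes, and the version was 3.0.2 per the file headers. The gene annotation they counted on is not given in the sources used here. The deposited matrices hold raw UMI counts, 1 per gene and barcode, for barcodes that the counting software had called as cells. A deposited table of both libraries together also holds counts, for a subset of these barcodes and 20210 of the 31053 genes. Its values were checked against the matrices, and 1485 of 34087726 non-zero entries differed, each being 0 in that table. No barcode with 20% or more mitochondrial UMIs was in it, and the other barcodes it left out had at least 7505 genes in the control library and 7509 in the dHet library. That table served as an alternative choice of cells. Gene positions were read from GENCODE annotation of GRCm38.

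Barcodes were kept with at least 500 detected genes and at most 20% mitochondrial UMIs. Doublets were scored per library with Scrublet as built into scanpy at an expected rate of 4%, and its automatic threshold removed 29 control barcodes (0.810%) and 42 dHet barcodes (1.05%). Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together without integration, on 2000 variable genes that excluded mitochondrial, ribosomal protein, haemoglobin and sex-linked genes as well as Irx3 and Irx5. The steps used 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1. Clusters were named from marker lists fixed before the data were examined. A name needed at least 3 of its markers in 25% or more of the cluster's cells. Among the 10 genes with the highest fold over cells outside the class (pseudocount 5 CPM, detected in at least 10% of the cluster's cells), no other class was allowed more markers than the named one. Classes other than neurons also needed a marker among the 10 leading genes over all other cells. A cluster with a median depth under 1/3 of its library's and no such marker stayed unnamed. Neuron clusters share their broad markers with most other cells here, so neurons were judged on the fold over non-neuronal cells. In 4 neuron clusters the leading genes over all cells held more markers of another class than of neurons, and the neuron share was also computed without them. A neuron type name needed at least 2 of its markers among those leading genes. Names therefore stand for marker-based likeness, and the authors' own cell annotation was not among the deposited files.

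With 1 library per genotype, cells are not replicates and no test across animals could be made. Shares of cells are given with exact Clopper-Pearson 95% intervals, UMI counts with exact Poisson intervals, and ratios (dHet over control) with exact conditional binomial intervals. Gene levels are UMIs summed over a class, divided by all UMIs of that class, in CPM (UMIs per 1e6 UMIs). Log2 ratios have 5 CPM added to each side, so they are smaller than the plain ratios for weakly expressed genes. Classes were compared where each library held at least 100 of their cells. The share of cells with a UMI of Mki67 or Top2a was taken after every cell had been thinned at random to 4000 UMIs, which left out 351 control and 235 dHet cells that were shallower. The median log2 ratio over expressed genes lay between -0.04 and -0.01 in all compared classes and over all kept cells, so no shift of all genes was removed.

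The rule for named genes was fixed before the data were examined. Irx3 and Irx5 came first. In each class, the 10 highest and 10 lowest log2 ratios were taken among genes with at least 200 UMIs over both libraries and a UMI in at least 10% of the class's cells in 1 library. Left out were mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, gene models named Gm plus digits or ending in Rik, and genes under 10% of their CPM in another class with at least 20 cells, which can come from free RNA. From each fixed list, up to 4 members with at least 50 UMIs and the largest size of log2 ratio were eligible, as were Lepr, Pomc, Agrp, Npy, Mki67, Top2a, Rax, Nes and Fto. The text names some of these genes. Other genes named in the closing section were chosen after their values were seen.

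The 22 fixed gene lists covered the Iroquois family, genomic neighbours of Irx3 and Irx5, the reporter and Cre driver, neural stem and radial glia genes, tanycyte genes, the cell cycle, proneural and immature neuron genes, leptin and melanocortin signalling, arcuate neuropeptides and amine synthesis, arcuate transcription factors, fast transmission and synapse, the Notch, Hedgehog, Wnt, and BMP and TGF-beta pathways, immediate early and dissociation response genes, myelin, cholesterol synthesis, the interferon response, mitochondrially encoded genes, haemoglobin and sex-linked genes. Of their symbols, 7 were absent from the files, among them tdTomato and Cre. A list was summarised by the median log2 ratio of members with at least 20 UMIs, with an order-statistic interval across members, and by the percentile of that median among 10000 random lists of equal size drawn from 20 bins of mean expression. The percentile describes these libraries and not the genotypes in general. Members are not independent, so neither the interval nor the percentile is a test.

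Alternatives changed 1 choice at a time, except that the stricter cell filter moved both of its limits together. They were at least 1000 genes with at most 10% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2, libraries aligned with ComBat, the cells of the authors' merged table, cells weighted equally, scaling by the median ratio, all cells thinned, pseudocounts of 1 and 20 CPM, list members with at least 100 UMIs or with no minimum, cycling cells without thinning, and cycling cells defined by 2 of 8 genes. Further ones, chosen after seeing the data, were clustering without the neuropeptide list, neurons without the 4 clusters named above, clusters of a class weighted equally, and cells between the 25th and 75th percentile of UMIs of their library. The minimum of 20 UMIs per list member was applied again after thinning, so thinned medians can rest on fewer members. Cells were clustered and named again under the stricter filter and with doublets kept, so a class could then hold other cells. The steps were tested on simulated counts with genes changed by 1.5, 2 and 3 fold. These class sums were drawn with counting error alone, independently for each gene, as the intervals assume. They held no clumping of UMIs in few cells, no linked genes and no differences between pools. The simulation therefore checks the computation and cannot show that the intervals are wide enough for the real libraries. At 1.5 fold the interval lay on the correct side of 1 for between 89.6% (Kiss1/Tac2-like) and 100% (all neurons) of the changed genes, and it held the true ratio for 95.0% to 95.6% of unchanged genes. For changed genes the interval held the true ratio in 92.5% (all neurons) to 96.5% (Sst-like) of cases. In each class, 40 of 40 simulated lists of 20 genes raised 1.3 fold lay above the 97.5th percentile of the random lists. Of 40 unchanged lists, from 0 (such as astrocyte-like) to 5 (Ghrh/Th/Gal-like) lay outside the central 95%. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, python-igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, with random seed 0.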

Results

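The libraries held cells marked by an Ins2-Cre-driven fluorescent reporter, sorted from the arcuate nucleus and median eminence at postnatal day 10. The arcuate nucleus contains the Agrp/Npy and Pomc neurons that regulate feeding, and the median eminence contains tanycytes, radial glia-like cells of the third ventricle with progenitor capacity. There was 1 control library and 1 dHet library, each from 1 pool of 5 mice. The control matrix held 3694 barcodes with 71174068 UMIs, and the dHet matrix held 4278 barcodes with 77288047 UMIs. After filtering, 3553 control cells with 70048514 UMIs and 3940 dHet cells with 74937937 UMIs remained. The median kept cell had 17387 UMIs and 5027 genes in the control library, and 17640.5 UMIs and 4983.5 genes in the dHet library. No replicate exists for either genotype, so every interval given covers counting error only and no difference could be set against variation between animals. The series title names postnatal hypothalamic neurogenesis and leptin sensitivity as the question, and the comparison is dHet against control throughout.

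Irx3 and Irx5, the 2 targeted homeobox genes, were both lower in the dHet library over all kept cells and in astrocyte-like cells. Astrocyte-like cells held most of the transcripts. In them, Irx3 was at 24.4 CPM in the control library and 7.45 CPM in the dHet library (61 and 21 UMIs), a ratio of 0.306 (0.177 to 0.509). Irx5 in the same class was at 42.3 and 23.8 CPM (106 and 67 UMIs), a ratio of 0.562 (0.407 to 0.770). Over all kept cells the ratios were 0.431 (0.292 to 0.628) for Irx3, from 91 and 42 UMIs, and 0.606 (0.475 to 0.769) for Irx5, from 179 and 116 UMIs.

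Outside astrocyte-like cells the counts were small. Ependymal-like cells carried Irx5 at 58.1 CPM in the control library and 39.6 CPM in the dHet library, with a ratio of 0.681 (0.353 to 1.3) whose interval took in 1. Tanycyte-like cells had 21 and 11 UMIs of Irx5, a ratio of 0.744 (0.324 to 1.61), and 6 and 0 UMIs of Irx3. All neuron-like cells together had 13 and 2 UMIs of Irx5 (0.139, 0.0152 to 0.615) and 8 and 2 UMIs of Irx3 (0.226, 0.0234 to 1.13), with 86.7% and 90% of them in 5 cells. Oligodendrocyte precursor-like cells went the other way, with 4 and 7 UMIs of Irx3 (2.42, 0.616 to 11.3) and 5 and 6 UMIs of Irx5 (1.66, 0.423 to 6.88), and both intervals took in 1. Pomc-like cells had 0 UMIs of either gene in both libraries. With every cell thinned to 4000 UMIs the Irx3 ratio was 0.230 over all cells and 0.148 in astrocyte-like cells. Irx1, a family member outside the targeted pair, had 28 and 32 UMIs in astrocyte-like cells, and over all kept cells the 4 measured members of the Iroquois family were all lower in the dHet library (median log2 ratio -0.18). Irx3 (ENSMUSG00000031734) lies on the minus strand of chromosome 8 at 91798525 to 91802067 (GRCm38), and Irx5 (ENSMUSG00000031737) on the plus strand at 92357625 to 92376286. The labels do not say which part of either gene was deleted. Because 3′ tags are counted, a tag from outside a deletion would still be counted for a mutant allele, so these ratios cannot serve as a check of the deletion.

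**Figure D1:**
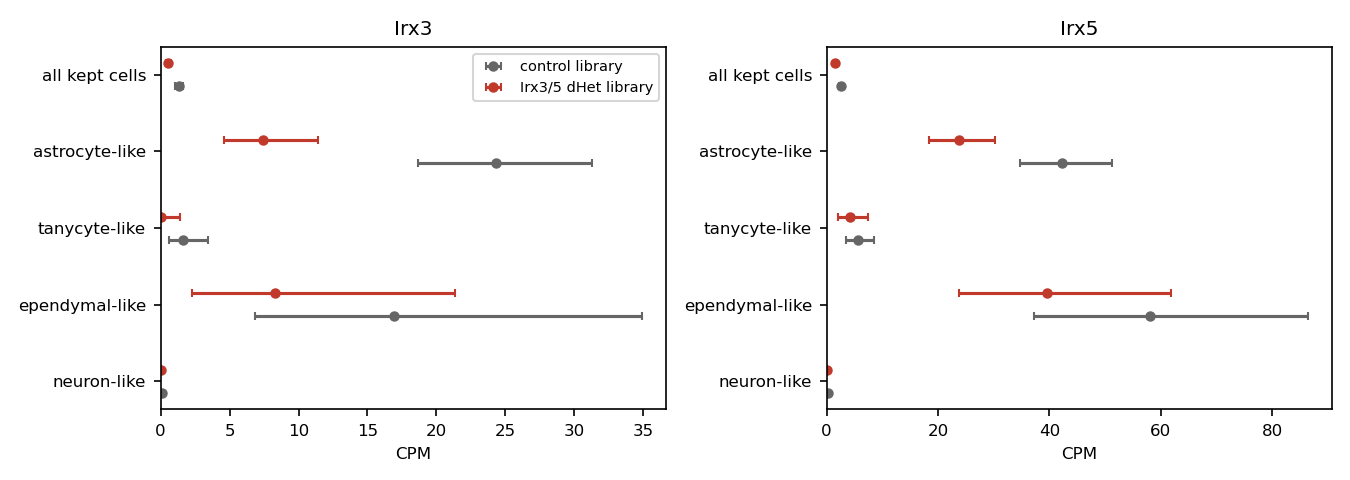
Level of Irx3 and Irx5 in CPM (horizontal axis) over all kept cells and in 4 cell classes, for the control library (grey) and the dHet library (red), with exact Poisson 95% intervals from the UMIs counted. In astrocyte-like cells both genes were lower in the dHet library, 24.4 against 7.45 CPM for Irx3 and 42.3 against 23.8 CPM for Irx5.

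The mix of cells differed between the libraries: neuron-like cells took a larger share of the dHet library and tanycyte-like cells a smaller one. Neuron-like cells were 67.1% of control cells (65.6 to 68.7) and 75.4% of dHet cells (74.0 to 76.7), from 2385 and 2969 cells. Tanycyte-like cells were 10.6% (9.56 to 11.6) and 7.11% (6.32 to 7.95), from 375 and 280 cells, a ratio of 0.673 (0.575 to 0.788). Pars tuberalis-like cells, an endocrine type of the pituitary stalk marked by Cga and Tshb, were 1.69% and 0.431%, a ratio of 0.256 (0.140 to 0.444). Astrocyte-like cells had similar shares, 11.6% (10.6 to 12.7) and 10.7% (9.71 to 11.7).

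Clusters within the tanycyte-like class also took smaller shares of the dHet library. The cluster led by Rax, Crym and S100a6 had a share ratio of 0.775 (0.637 to 0.942), and the one led by Scn7a and Cldn10 had 0.554 (0.394 to 0.774). Oligodendrocyte precursor-like cells were 2.59% and 1.95%, a ratio of 0.755 (0.550 to 1.03), and oligodendrocyte-like cells had a ratio of 1.17 (0.710 to 1.95). Ependymal-like cells had a ratio of 0.870 (0.493 to 1.53). These 3 intervals took in 1. At Leiden resolution 2 the ependymal-like class grew to 72 and 46 cells, with a ratio of 0.576 (0.389 to 0.846), and the oligodendrocyte precursor-like interval lay below 1 with doublets kept (0.537 to 0.996) and with the merged table (0.530 to 0.989). Without the 4 neuron clusters whose leading genes over all cells pointed elsewhere, neuron-like cells were 51.4% and 56.6%, a ratio of 1.10 (1.04 to 1.17). Among cells between the 25th and 75th percentile of UMIs, the ratio was 0.369 for tanycyte-like and 0.136 for pars tuberalis-like cells, and at Leiden resolution 0.5 it was 0.444 for pars tuberalis-like cells. Unnamed cells, most of them shallow, were 3.80% and 2.01%. Shares depend on how the tissue was dissected and sorted as well as on its make-up, and a smaller share of 1 class raises the shares of all others.

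Among neuron-like cells, both feeding-related types took larger shares of the dHet library. Agrp/Npy-like cells, which promote feeding, were 7.42% of control neurons (6.40 to 8.55) and 11.2% of dHet neurons (10.1 to 12.4), from 177 and 334 cells, a ratio of 1.52 (1.26 to 1.83). Pomc-like cells, which restrain feeding, were 4.44% (3.65 to 5.35) and 6.94% (6.05 to 7.91), from 106 and 206 cells, a ratio of 1.56 (1.23 to 1.99). The other 3 arcuate types gave intervals among neuron-like cells that took in 1. Their ratios were 1.16 (0.969 to 1.39) for Ghrh/Th/Gal-like, 0.971 (0.774 to 1.22) for Sst-like and 0.767 (0.581 to 1.01) for Kiss1/Tac2-like cells. The Kiss1/Tac2-like interval lay below 1 at Leiden resolution 2 (0.572 to 0.995), with ComBat (0.567 to 0.986), with doublets kept (0.575 to 0.999) and with the cells of the merged table (0.547 to 0.951).

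Over all kept cells the ratio was 1.70 (1.41 to 2.05) for Agrp/Npy-like and 1.75 (1.38 to 2.24) for Pomc-like cells, and that of Ghrh/Th/Gal-like cells, 1.3 (1.09 to 1.56), then also lay above 1. Clusters of neurons without a type name also differed in size. A cluster led by Foxb1 had a ratio of 1.61 (1.07 to 2.45) among neuron-like cells, although its leading genes over all cells held 3 pars tuberalis or pituitary markers and 0 neuron markers, and one led by Adcyap1 and Tac1 had 1.42 (1.02 to 1.98). Lower shares were found for a cluster with Slc17a6, Bsx and Cartpt, at 0.629 (0.501 to 0.789), for one with Bcl11b, Pthlh and Otp, at 0.679 (0.546 to 0.843), and for one with Tbx19, Tg and Cartpt, at 0.697 (0.559 to 0.868). At Leiden resolution 0.5 the Pomc-like class grew to 286 and 349 cells and its ratio was 0.982 (0.838 to 1.15), whereas at resolution 2 it held 84 and 178 cells with a ratio of 1.68 (1.29 to 2.20). At resolution 2 the Sst-like class kept only 15 and 12 cells, with a ratio of 0.632.

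**Figure D2:**
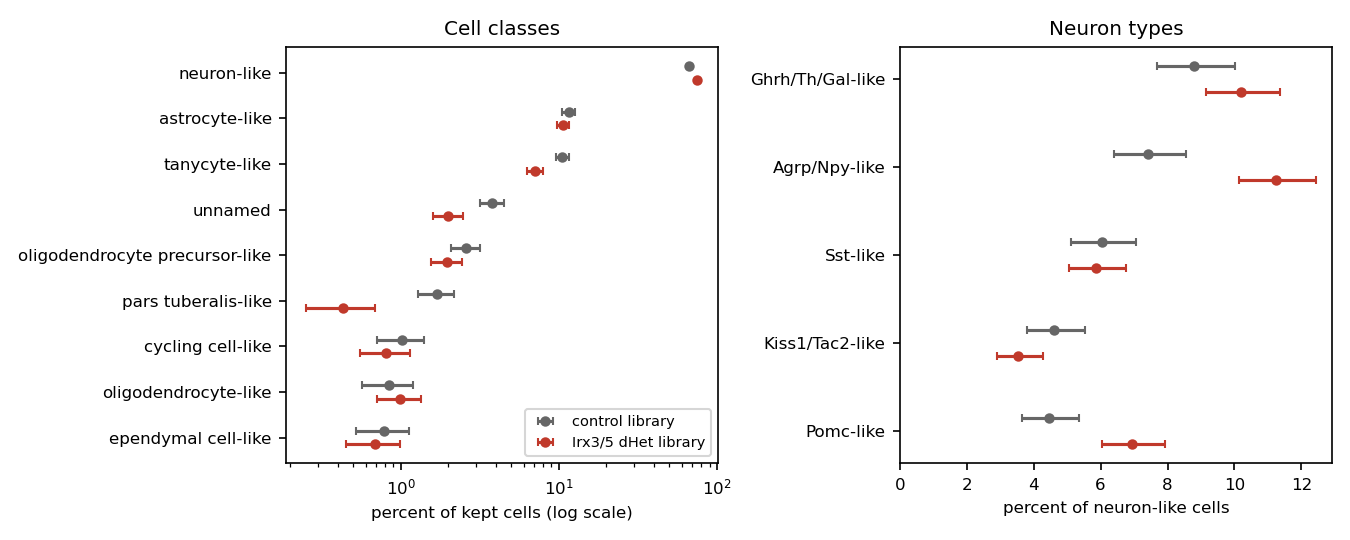
Share of each cell class in percent of kept cells on a log axis (left) and share of each neuron type in percent of neuron-like cells (right), for the control library (grey) and the dHet library (red), with Clopper-Pearson 95% intervals. The intervals of the libraries are apart for neuron-like, tanycyte-like, pars tuberalis-like, Agrp/Npy-like and Pomc-like cells, and for unnamed cells.

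Cycling cells were rare in both libraries, with similar shares. At 4000 UMIs per cell, a UMI of Mki67 or Top2a, 2 genes of dividing cells, was seen in 53 of 3202 control cells (1.66%, 1.24 to 2.16) and 63 of 3705 dHet cells (1.70%, 1.31 to 2.17), a ratio of 1.03 (0.702 to 1.51). Tanycyte-like cells had 2 of 345 (0.580%) and 1 of 255 (0.392%), which cannot be told apart within counting error from the background of 0.433% and 0.586% in neuron-like cells, a class that should lack both genes. Astrocyte-like cells had 0 of 308 (Clopper-Pearson upper bound 1.19%) and 2 of 347 (0.576%). Oligodendrocyte precursor-like cells had 7 of 78 (8.97%) and 7 of 70 (10.0%). A separate cycling cell-like cluster held 36 and 32 cells, a share ratio of 0.802 (0.482 to 1.33). Median depths before thinning were 10242 and 8367 UMIs in the tanycyte-like cells used and 24248 and 21760 in the neuron-like cells.

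Without thinning the ratio over all cells was 0.627 (0.489 to 0.801), with 4.11% of control neurons and 1.82% of dHet neurons holding such a UMI. In neuron-like cells Mki67 had 89 and 39 UMIs, a ratio of 0.396 (0.265 to 0.584), whereas Top2a had a ratio of 0.904 (0.423 to 1.93) there. Requiring 2 of 8 cycle genes gave 47 and 42 cells, a ratio of 0.772 (0.497 to 1.2). In astrocyte-like cells Mki67 had 0 and 10 UMIs, with a lower bound of the ratio of 1.99 but all UMIs in 5 cells, and Top2a had 4 and 8 UMIs (1.78, 0.476 to 8.06). A difference in division among tanycyte-like cells could not be measured here. Few UMIs were seen, and cell cycle genes were not excluded from the clustering. Dividing cells formed their own cluster led by Top2a and Mki67, so a dividing tanycyte could be counted there and not in the tanycyte-like class.

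Tanycyte-like cells of the dHet library had less transcript of immediate early and heat shock genes, and less Gfap and C4b. The heat shock gene Hspa1a was at 413 and 73.4 CPM (0.178, 0.153 to 0.207) and Hspa1b at 408 and 91.5 CPM (0.224, 0.195 to 0.257). Cyr61, a matricellular gene induced by mechanical and growth signals, had a ratio of 0.263 (0.230 to 0.299). Gfap, the intermediate filament of reactive glia, was at 155 and 42.6 CPM (0.275, 0.223 to 0.337), and the complement gene C4b had a ratio of 0.341 (0.257 to 0.447). Genes that were higher included Dtna, a dystrobrevin, at 129 and 223 CPM (1.73, 1.53 to 1.95), the kinase gene Wnk2 (1.68, 1.40 to 2.02) and Lypd1 (1.85, 1.48 to 2.33). Of the UMIs of Lypd1, 24.5% were in 5 cells, and of those of Gfap, 23.2%.

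Of the immediate early and dissociation response list, 29 of 31 measured members were lower in tanycyte-like cells, with a median log2 ratio of -0.59 (-0.97 to -0.34). Fos had a ratio of 0.419 (0.395 to 0.445), Jun 0.451 and Egr1 0.449. The tanycyte list had no common direction, with 11 of 23 members higher and a median of -0.04 (-0.14 to 0.10) that lay at 0.09 with clusters weighted equally and at -0.16 with cells weighted equally. Within it, the thyroid hormone transporter gene Slco1c1 had a ratio of 0.472 (0.386 to 0.574), Cd59a 0.653 and Scn7a 0.696. Scn7a, Cyr61 and Hes1 are leading genes of the tanycyte-like cluster led by Scn7a and Cldn10, whose share was smaller in the dHet library. Their lower levels can therefore reflect the mix of clusters in part. Rax, a homeobox gene that marks tanycytes, was at 234 and 199.99 CPM (0.855, 0.766 to 0.953), and Nes, a progenitor filament gene, at 106 and 117 CPM (1.11, 0.953 to 1.29). Neural stem and radial glia genes were lower in 16 of 26 cases, with a median of -0.12 (-0.22 to 0.10). Among them were Hes1 (0.681, 0.625 to 0.742) and Hopx (0.693, 0.592 to 0.809). Cell cycle members split 7 to 6 with a median of 0.04, although Hmgb2, a chromatin gene of that list, was higher (1.85, 1.52 to 2.26).

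Gfap in tanycyte-like cells moved to a log2 ratio of -0.82 under the stricter cell filter and to -1.08 with clusters weighted equally, against -1.75 as reported. The receptor gene Tnfrsf19 was higher at 61.0 and 122 CPM, but 27.0% of its UMIs were in 5 cells, and its log2 ratio of 0.95 became -0.02 with cells weighted equally and -0.14 under the stricter filter.

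Astrocyte-like cells of the dHet library had more transcript of Txnip, Mfsd2a, Acss2 and cholesterol synthesis genes, and less of the Hedgehog pathway. Txnip, an arrestin-like gene induced by glucose that limits its uptake, was at 6.39 and 71.3 CPM (16 and 201 UMIs), a ratio of 11.2 (6.71 to 19.9). Mfsd2a, a lipid transporter gene, was at 36.3 and 83.7 CPM (2.30, 1.80 to 2.97), and Acss2, which makes acetyl-CoA from acetate, at 68.7 and 148 CPM (2.15, 1.80 to 2.59). Il17rd, an inhibitor of FGF signalling, was lower at 99.4 and 39.7 CPM (0.400, 0.317 to 0.501), as were the FGF receptor-like gene Fgfrl1 (0.516, 0.415 to 0.641) and the FGF feedback gene Spry2 (0.580, 0.486 to 0.692).

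Cholesterol synthesis genes were higher in 17 of 20 cases, with a median log2 ratio of 0.31 (0.22 to 0.47) at percentile 100 of the random lists. Insig1, Stard4, Mvd and Lss had ratios of 1.65, 1.58, 1.51 and 1.52. All 12 measured Hedgehog pathway members were lower (median -0.31, -0.55 to -0.13, percentile 0.07). The repressor gene Sufu had a ratio of 0.581 (0.403 to 0.832), the transcription factor genes Gli3 0.626 (0.493 to 0.792) and Gli1 0.631 (0.437 to 0.907), and the receptor gene Ptch1 was at 608 and 465 CPM (0.764, 0.709 to 0.823). Notch pathway members were lower in 12 of 15 cases (median -0.11, -0.40 to -0.02), but at percentile 8.75 this median was not extreme among random lists. Jag1 was at 0.410 (0.242 to 0.677), Maml2 at 0.549 and Hes1 at 0.719. Interferon response genes were higher in 14 of 15 cases (median 0.31, 0.02 to 0.53), among them Ifitm3 (2.14, 1.42 to 3.30), with 32.8% of its UMIs in 5 cells, and Stat2 (1.52, 1.12 to 2.09). Neural stem and radial glia genes had a median of -0.10 (-0.22 to 0.04) in this class.

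The immediate early list in astrocyte-like cells had a median of -0.05 (-0.46 to 0.22), with 13 of 24 members lower. Gfap was higher at 159 and 329 CPM, but 62.2% of its UMIs were in 5 cells, and its log2 ratio of 1.03 was 0.13 after thinning. With a pseudocount of 20 CPM the log2 ratio of Txnip was 1.79 in place of 2.74.

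Agrp/Npy-like cells of the dHet library had more transcript of the leptin receptor gene Lepr and of Zbtb16, Cdkn1a and Pik3r1, and less of immediate early genes, while Agrp and Npy themselves were nearly level. Lepr was at 12.4 and 23.8 CPM (68 and 215 UMIs), a ratio of 1.93 (1.46 to 2.57). Zbtb16, a zinc finger transcription factor gene, was at 2.73 and 24.4 CPM (8.93, 5.30 to 16.2), and Cdkn1a, the cell cycle inhibitor p21, at 5.83 and 34.6 CPM (5.94, 4.12 to 8.83). Pik3r1, a regulatory subunit of PI3-kinase, was at 24.9 and 59.5 CPM (2.39, 1.97 to 2.90). Fos was lower, at 391 and 76.4 CPM (0.195, 0.179 to 0.213), and so was the activity-dependent transcription factor gene Npas4, at 36.8 and 2.66 CPM (0.0723, 0.0453 to 0.111).

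Leptin and melanocortin signalling genes were higher in 19 of 26 cases in Agrp/Npy-like cells, with a median log2 ratio of 0.15 (0.03 to 0.24, percentile 99.97). Foxo1, which acts downstream of insulin and leptin, had a ratio of 1.29 (1.16 to 1.44). Socs3, a feedback inhibitor of the leptin receptor that is also an immediate early gene, was lower at 44.6 and 19.1 CPM (0.427, 0.350 to 0.522). Agrp was at 5265 and 5308 CPM (1.01, 0.994 to 1.02), a log2 ratio of 0.01 that turned to -0.07 with cells weighted equally and to -0.09 after thinning. Npy was at 18488 and 18069.5 CPM (0.977, 0.970 to 0.985). Alkal2, a ligand gene of the ALK receptor, had a ratio of 2.39, the activin receptor gene Acvr1c 1.99, the chemokine gene Ccl17 2.16 and the G-protein regulator gene Rgs4 1.95.

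The immediate early list was lower in 22 of 27 cases in this class, with a median of -0.91 (-1.44 to -0.12). Jun had a ratio of 0.358 (0.332 to 0.386), Gadd45g 0.282 (0.242 to 0.326), and Hspa1b 0.121 (0.0913 to 0.158) with 46.2% of its UMIs in 5 cells. The arginase gene Arg2 was at 43.2 and 11.8 CPM (0.272, 0.215 to 0.344), and Dbp, an output gene of the circadian clock, at 108 and 49.3 CPM (0.457, 0.403 to 0.518). Interferon response genes were lower in 9 of 10 cases (median -0.32, -0.46 to -0.09), with Ifi27 at 0.628 and Irf9 at 0.679. Cholesterol synthesis genes were lower in 13 of 20 cases (median -0.17, -0.26 to 0.06, percentile 0.02), with Idi1 at 0.698 and Msmo1 at 0.748. Among arcuate transcription factors, Nr0b1 had a ratio of 0.546 (0.451 to 0.661).

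After thinning, the log2 ratios in Agrp/Npy-like cells were 1.72 for Lepr (0.73 as reported), 1.60 for Acvr1c (0.94 as reported), 0.06 for Nptx2 (0.85 as reported) and 0.00 for Msmo1 (-0.40 as reported). With a pseudocount of 20 CPM they were 0.97 for Zbtb16, 1.08 for Cdkn1a, -1.33 for Npas4 and -1.55 for Hspa1b, against 1.93, 1.87, -2.45 and -2.40, and with 1 CPM they were 2.77 for Zbtb16 and -3.37 for Npas4.

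Pomc-like cells of the dHet library had more transcript of cholesterol synthesis genes, Sv2c, Ogt and Kcna5, and Pomc itself was close to level. Pomc was at 5018 and 5045 CPM (1.01, 0.987 to 1.02). Sv2c, a synaptic vesicle gene, was at 33.7 and 60.2 CPM (1.78, 1.44 to 2.22), Ogt, which attaches O-GlcNAc to proteins, at 71.3 and 122 CPM (1.71, 1.47 to 1.98), and the potassium channel gene Kcna5 had a ratio of 1.84 (1.35 to 2.54). The glypican gene Gpc3 was lower at 57.7 and 27.6 CPM (0.478, 0.387 to 0.591). Cholesterol synthesis genes were higher in 17 of 20 cases, with a median log2 ratio of 0.14 (0.08 to 0.19), among them Fdps (1.27, 1.15 to 1.41) and Insig1 (1.27, 1.02 to 1.59).

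Lepr in Pomc-like cells had only 13 and 25 UMIs, a ratio of 1.08 (0.532 to 2.30), so a difference was not detectable. The leptin and melanocortin list had a median of -0.03 (-0.09 to 0.07) there and -0.10 after thinning. Immediate early genes had a median of -0.15 (-0.54 to 0.01). After thinning it was 0.13 over the members that still had at least 20 UMIs, a set that can be smaller. Junb had a ratio of 0.344 (0.272 to 0.434) and Fos 0.492 (0.418 to 0.579), with 27.5% and 28.4% of their UMIs in 5 cells. BMP and TGF-beta pathway members were higher in 8 of 10 cases (median 0.21, -0.14 to 0.47). Id2, a target of that pathway, was lower (0.435, 0.282 to 0.666), with a log2 ratio of -0.81 that was -1.47 with cells weighted equally and -1.82 after thinning. Rgs7bp had a log2 ratio of -0.68 that was -1.32 after thinning. The log2 ratio of Pomc, 0.01, was -0.04 with doublets kept and -0.18 under the stricter cell filter.

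Sst-like cells had less Lrp1b, a lipoprotein receptor gene, at 74.4 and 34.2 CPM (0.460, 0.370 to 0.571), and more of the growth hormone receptor gene Ghr (1.57, 1.17 to 2.12). In these cells Wasl had a ratio of 0.588 (0.488 to 0.706), Hint3 had 1.60 (1.2 to 2.14), and Lepr had 10 and 2 UMIs (0.190, 0.0202 to 0.891), with 75% of them in 5 cells. Lepr had 19 and 16 UMIs in Ghrh/Th/Gal-like cells (0.684, 0.329 to 1.40). Ghrh/Th/Gal-like cells had less Cartpt, a peptide gene, at 561 and 348 CPM (0.620, 0.588 to 0.655), and less of the serotonin receptor gene Htr2c (0.491, 0.370 to 0.648). In them Slc18a3, the vesicular acetylcholine transporter gene, had a ratio of 1.56 (1.32 to 1.86). Crhbp (2.09) and Grp (0.434) also differed there, with 35.6% and 49.6% of their UMIs in 5 cells. Kiss1/Tac2-like cells had less of the phosphodiesterase gene Pde10a, at 129 and 50.3 CPM (0.391, 0.303 to 0.500), of the sodium channel gene Scn2b (0.552, 0.406 to 0.743) and of Vgf, a secreted neuropeptide precursor gene, at 257 and 157 CPM (0.609, 0.524 to 0.706). The immediate early list had medians of -0.18 (-0.42 to -0.02) in Sst-like, -0.21 (-0.45 to -0.04) in Ghrh/Th/Gal-like and -0.26 (-0.48 to 0.00) in Kiss1/Tac2-like cells.

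Over all neuron-like cells, Npas4 and immediate early genes were lower in the dHet library, and proneural and immature neuron genes were slightly lower over the pooled class, though not within each neuron type. Npas4 was at 35.5 and 9.0 CPM (0.253, 0.231 to 0.277), Fos at 203 and 67.2 CPM (0.331, 0.320 to 0.343) and Junb at 87.8 and 35.5 CPM (0.405, 0.386 to 0.425). The stress-inducible gene Gadd45g was at 78.2 and 39.4 CPM (0.504, 0.480 to 0.528), and Nrgn, a calmodulin-binding protein gene, at 534 and 350.0 CPM (0.656, 0.645 to 0.667). Avp, the vasopressin gene, was higher at 160.4 and 394 CPM (2.46, 2.40 to 2.52), with 35.6% of its UMIs in 5 cells. The cadherin gene Cdh15 (2.80, 2.47 to 3.19) and Ghr (1.77, 1.67 to 1.87) were also higher. Ghr is a leading gene of the Agrp/Npy-like cluster, and outside that type its ratio was 1.37 (1.26 to 1.49), while that of Cdh15 was 2.71 (2.38 to 3.10). Rgs16 was lower (0.519, 0.483 to 0.557).

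Of the proneural and immature neuron list, 22 of 26 members were lower, with a median log2 ratio of -0.09 (-0.14 to -0.05, percentile 1.16), among them Insm1 (0.741, 0.681 to 0.806), Dlx6os1 (0.745, 0.678 to 0.817) and Bcl11a (0.805, 0.764 to 0.848). Within the neuron types, whose mix differed between the libraries, the list had medians of 0.07 in Pomc-like (13 of 21 higher), 0.00 in Agrp/Npy-like, -0.02 in Sst-like, -0.04 in Ghrh/Th/Gal-like and -0.02 in Kiss1/Tac2-like cells. Wnt pathway members were lower in 16 of 19 cases (median -0.09, -0.18 to -0.03, percentile 0.27), with Lef1 at 0.670 and Dkk3 at 0.677. Within types that list had medians of 0.01 in Pomc-like (7 of 11 higher) and Sst-like cells (5 of 9 higher), -0.13 in Agrp/Npy-like, -0.06 in Ghrh/Th/Gal-like and -0.04 in Kiss1/Tac2-like cells, all with intervals that took in 0. Cell cycle members were lower in 20 of 27 cases (median -0.05, -0.06 to -0.01, and -0.09 after thinning), with Pcna at 0.722 (0.653 to 0.799). Immediate early genes were lower in 25 of 31 cases (median -0.36, -0.62 to -0.04). Lepr was at 2.55 and 4.51 CPM (1.77, 1.45 to 2.16), a log2 ratio of 0.33 that was 0.09 with clusters weighted equally. Neuron-like cells outside the Agrp/Npy-like type had 86 and 86 Lepr UMIs (0.951, 0.697 to 1.3), so the pooled difference came from that type, whose share was also larger.

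Mitochondrially encoded and sex-linked genes are given further below, and the other lists had medians between -0.09 and 0.12 in neuron-like cells. Leptin and melanocortin signalling had 0.04 (-0.05 to 0.10, percentile 99.6), which turned to -0.01 with cells weighted equally. Medians were -0.09 (-0.16 to 0.05, percentile 0.38) for arcuate transcription factors, -0.06 for fast transmission and synapse, -0.03 for the Notch and for the Hedgehog pathway, 0.00 for the BMP and TGF-beta pathway and -0.03 for myelin (-0.09 after thinning). They were 0.03 for cholesterol synthesis, -0.03 for the interferon response, -0.05 for neural stem and radial glia genes and -0.05 for tanycyte genes, which lay at 0.02 with clusters weighted equally. Arcuate neuropeptides and amine synthesis had a median of 0.12 (-0.01 to 0.36, percentile 100). The reporter list was measured through Ins2 alone, with 57 and 42 UMIs (0.666, 0.436 to 1.01), and the haemoglobin list through 1 gene with a log2 ratio of -0.02.

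**Figure D3:**
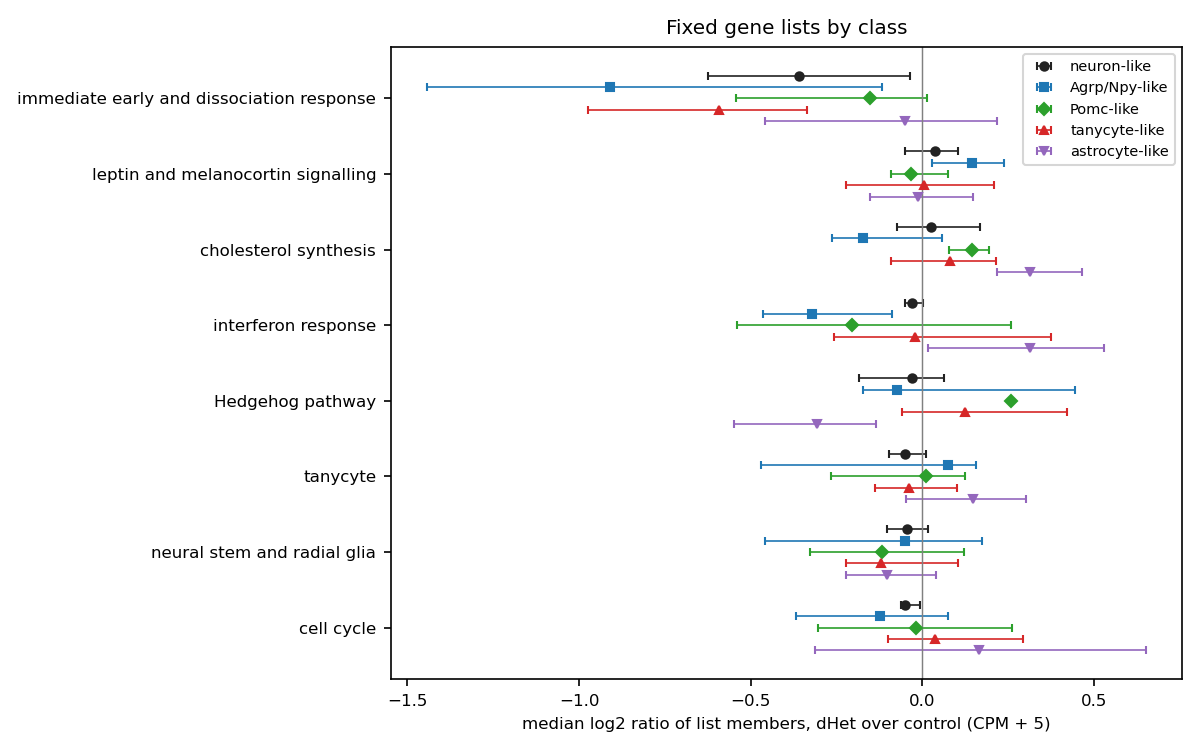
Median log2 ratio (dHet over control, CPM plus 5) of the measured members of 8 fixed gene lists in 5 cell classes, with order-statistic intervals across members and a line at 0; the Hedgehog list in Pomc-like cells rests on 2 members and has no interval. Immediate early genes lie furthest below 0 in Agrp/Npy-like (-0.91) and tanycyte-like cells (-0.59), and cholesterol synthesis lies above 0 in astrocyte-like (0.31) and Pomc-like cells (0.14).

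Some differences ran through most classes. Gstp1, a glutathione transferase gene, was higher in all 8 compared classes, at 14.1 and 36.5 CPM over all kept cells (2.60, 2.41 to 2.80). Tpm3-rs7, a gene related to the tropomyosin gene Tpm3, was lower at 52.3 and 19.6 CPM (0.374, 0.352 to 0.398), while Tpm3 itself had a ratio of 1.18 (1.15 to 1.21). The transcript AC160336.1 had a ratio of 0.504 (0.479 to 0.530) in neuron-like cells. Mitochondrially encoded genes were higher in 12 of 13 cases in neuron-like cells (median 0.41, 0.16 to 0.55), at 0.28 in tanycyte-like and -0.01 in astrocyte-like cells, and kept cells had a median mitochondrial share of 4.69% and 5.97%. Sex-linked genes went different ways, with a median of -0.30 (-0.56 to 0.26) in neuron-like, -0.59 (-0.74 to 0.03) in astrocyte-like, 0.25 (-0.26 to 0.50) in tanycyte-like and 0.10 in Agrp/Npy-like and Kiss1/Tac2-like cells, and Y-linked Eif2s3y was at 43.4 and 27.9 CPM in neuron-like cells. The list mixes Xist and Tsix with Y-linked genes, so its median is no measure of a difference in sex. The labels do not give the sex of the pooled animals. A different mix of sexes in the pools is therefore not excluded and cannot be told apart from the genotype. Neuropeptide genes were higher in 10 of 12 cases in tanycyte-like and 8 of 9 cases in astrocyte-like cells, classes that do not make most of these peptides. Agrp had 17 and 42 UMIs in astrocyte-like cells.

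Fto, the neighbouring gene whose introns hold obesity-associated variants linked to Irx3 and Irx5, was close to level over all kept cells, at 58.6 and 63.8 CPM (1.09, 1.04 to 1.13). It was higher in Agrp/Npy-like (1.31, 1.14 to 1.52) and Pomc-like cells (1.25, 1.04 to 1.51) and lower in astrocyte-like cells, at 78.2 and 54.6 CPM (0.698, 0.561 to 0.866). In tanycyte-like cells the ratio was 1.22 (0.984 to 1.5), with a log2 ratio of 0.26 that turned to -0.11 with cells weighted equally and -0.02 under the stricter filter, where the class held fewer cells. Fto (ENSMUSG00000055932) lies on the plus strand of chromosome 8 at 91313525 to 91668439. The 24 measured neighbours of Irx3 and Irx5 had a median log2 ratio of -0.07 (-0.14 to 0.03) in neuron-like cells, with 16 lower, and in tanycyte-like cells 15 of 22 were higher (median 0.13, -0.10 to 0.26). Lepr (ENSMUSG00000057722) lies on the plus strand of chromosome 4 at 101717404 to 101815352.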

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

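The limits that picked the 5 gene pairs below were chosen after the results were seen, and the differences between classes were not tested. For 31 pairs of classes, a gene singled out in the first class had counting intervals on opposite sides of 1. Of these, 5 had a log2 ratio of at least 0.5 in size in both classes, at least 200 UMIs in the second class, and a level there of at least 10% of the highest class. With 1 library per genotype, counting error is the only error these intervals cover.

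Gfap was lower in tanycyte-like cells of the dHet library (log2 ratio -1.75) and higher in astrocyte-like cells (1.03), a difference of -2.78. In astrocyte-like cells 62.2% of the Gfap UMIs were in 5 cells, and the log2 ratio there was 0.13 after thinning and 0.47 with cells weighted equally, both under the limit of 0.5. In tanycyte-like cells the log2 ratio of Gfap was -0.82 under the stricter filter, where the class held fewer cells, and -1.08 with clusters weighted equally. Tac1 was higher in Pomc-like cells (0.89, with 41.0% of its UMIs in 5 cells) and lower in Ghrh/Th/Gal-like cells (-0.61), a difference of 1.5. Tac1 was also higher in Agrp/Npy-like cells (1.33, from 5.83 and 22.3 CPM, with 63.5% of its UMIs in 5 cells), a difference of 1.94 from Ghrh/Th/Gal-like cells. A cluster outside these 2 types held Tac1 at 1673 CPM, so free RNA or mixed droplets are not excluded as the source of the low levels in Agrp/Npy-like cells (5.83 and 22.3 CPM) and Pomc-like cells (31.4 and 62.4 CPM). Ube2ql1 was lower in Sst-like cells (-0.65) and higher in Pomc-like cells (0.56), a difference of -1.21. Vgf was lower in Kiss1/Tac2-like cells (-0.70) and higher in Agrp/Npy-like cells (0.52), a difference of -1.22.

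Barcodes that the comparisons did not use also differed. Those with over 20% mitochondrial UMIs were 5.98% of the dHet barcodes (5.29 to 6.74), against 2.0% of the control barcodes (1.58 to 2.51).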

How the results depend on the processing

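No paired analysis was possible because each genotype had 1 pooled library and no label links animals of the pools. Variation between animals, dissections and sorts could not be measured with these libraries. Depth limits further values: Lepr outside Agrp/Npy-like cells, Irx3 and Irx5 outside astrocyte-like cells, and Mki67 or Top2a in glia rest on few UMIs. Over the alternatives, 92 of 102 share and cycling ratios, 18 of 20 Irx ratios, 686 of 707 list medians and 741 of 904 gene ratios stayed within the counting interval (for lists, the interval across members) of the reported value. The direction was as reported in 95, 20, 614 and 894 of them. Unless a size shows the cause below, the cause was not tested. Oligodendrocyte precursor-like and cycling cell-like classes were not found under the stricter filter, at Leiden resolution 0.5 or with ComBat, and no Sst-like class was found without the peptide genes, so these gave no value.

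Among values whose interval lay off no difference, the directions that turned were those of the Pomc share, 0.982 at Leiden resolution 0.5, where the class took in other neurons and held 286 and 349 cells, of Tnfrsf19 in tanycyte-like cells, -0.0171 with cells weighted equally and -0.14 under the stricter filter, and of Msmo1 in Agrp/Npy-like cells, 0.00086 after thinning. Under the stricter filter the tanycyte-like class was named anew and held fewer cells. The other turns were of values whose interval took in no difference, such as Fto in tanycyte-like cells, Agrp in Agrp/Npy-like cells, and immediate early genes and Pomc in Pomc-like cells. The Ghrh/Th/Gal share, 1.16 as reported, had an interval above 1 with the cells of the merged table (1.22) and between the depth percentiles (1.35, chosen after seeing the data). That of Kiss1/Tac2, 0.767 as reported, had an interval below 1 at resolution 2 (0.755), with ComBat (0.748), with doublets kept (0.758) and with the merged table (0.722). The ependymal cell share, 0.870 as reported, had one below 1 at resolution 2 (0.576), and that of oligodendrocyte precursor cells, 0.755 as reported, with doublets kept (0.733), with the merged table (0.725) and between the depth percentiles. Among cells between the 25th and 75th percentile of UMIs, chosen after seeing the data, share ratios were 0.756 for astrocyte, 1.19 for neuron, 0.267 for oligodendrocyte precursor, 0.136 for pars tuberalis, 0.369 for tanycyte and 1.94 for Agrp/Npy cells. That choice leaves out shallow and deep cells by its construction. Pars tuberalis was at 0.444 at resolution 0.5, and Sst was at 0.632 at resolution 2, with 15 and 12 cells. Cycling cells without thinning gave 0.627. Irx3 after thinning gave 0.230 over all cells and 0.148 in astrocyte-like cells.

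After thinning, list medians moved most in Pomc-like cells: -0.46 for tanycyte, -0.10 for leptin and melanocortin signalling, -0.0885 for fast transmission and synapse, -0.30 for Notch pathway, -0.43 for Wnt pathway, 0.13 for immediate early and dissociation response and 0.27 for myelin genes. Thinned medians cover only members that still had at least 20 UMIs, so they can move through the loss of members as well as through levels. Thinned medians in other classes were -0.0905 for cell cycle and -0.0926 for myelin in neuron-like cells, -0.16 for cell cycle and -0.21 for BMP and TGF-beta pathway in tanycyte-like cells, -0.0602 for fast transmission and synapse and -0.79 for sex-linked genes in astrocyte-like cells. In Agrp/Npy-like cells they were -0.41 for Hedgehog pathway, -0.34 for myelin and -0.57 for interferon response. Other settings gave 0.0210 for tanycyte genes in neuron-like cells with clusters weighted equally (chosen after seeing the data), -0.16 for tanycyte genes in tanycyte-like cells with cells weighted equally, 0.18 for arcuate neuropeptides and amine synthesis in astrocyte-like cells with no minimum, 0.27 for fast transmission and synapse in tanycyte-like cells with doublets kept, and 0.20 for cholesterol synthesis in Pomc-like cells under the stricter filter.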

Other observations

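Neuron clusters without a type name, described by their leading genes, were also compared in size after the clusters were seen. A cluster led by Vip, Avp, Rgs16 and Prok2 had 131 control and 174 dHet cells, a share ratio among neuron-like cells of 1.07 (0.846 to 1.35). A cluster led by Ppp1r17 and Pdyn had 117 and 108 cells, a ratio of 0.742 (0.566 to 0.972). An unnamed cluster led by the keratin genes Krt14 and Krt5 held 3 control and 14 dHet cells.

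In the tests that follow, those of the stricter filter, of gene copies, of glucocorticoid-induced genes and of clock genes were fixed before their results were seen, and the others were chosen afterwards, as was the change per list member used to judge the stricter filter. The prediction on gene copies was written jointly for Gstp1 and Tpm3-rs7 and was split by gene after the values were seen, with its bounds kept.

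Agrp/Npy-like and Pomc-like cells took larger shares of the dHet neurons. More of the arcuate nucleus as a whole in the dHet dissection is argued against by the Kiss1/Tac2-like share ratio of 0.767, whose upper bound of 1.01 lay below the lower bound of 1.26 for Agrp/Npy-like cells. This type was picked after its value was seen. The Sst-like interval (0.774 to 1.22) also lay below that bound. The Ghrh/Th/Gal-like ratio of 1.16 (0.969 to 1.39) did not, so that arcuate type does not argue against the explanation. Peptide genes setting cluster membership directly is argued against by ratios of 1.48 and 1.52 for the Agrp/Npy-like and Pomc-like classes when clustered without them. The resulting clusters were still named with peptide markers, and genes expressed together with the peptides still entered the clustering. Dissections that took in different neighbouring regions remain a candidate explanation, since the pars tuberalis-like ratio was 0.256 and that of the Foxb1 cluster 1.61, a cluster whose leading genes over all cells did not support its neuron name. Both groups were picked after their shares were seen, so they decide little. Not all neuron clusters without a type name differed. The one led by Vip and Avp had 1.07 (0.846 to 1.35), and the one led by Fezf1 and Cbln1 had 0.902 (0.722 to 1.13). The Irx3/5 genotype stays open and untested, because it differs between the pools just as the dissection does.

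Immediate early and heat shock genes were lower in the dHet library in most classes. Lower neuronal activity alone is argued against by tanycyte-like cells, where the list's median was -0.59. Tissue handling that acted on all cell classes alike was weighed with astrocyte-like cells. Their median was -0.0515 (-0.46 to 0.22), an interval that also held the neuron-like median of -0.36. Beyond counting error, 7 members were lower there and 6 higher, and 3 of the higher ones were lowered in neuron-like cells. Members lay above their value in neuron-like cells by a median of 0.33 (0.12 to 0.64, 24 members). Over the 14 members with at least 100 UMIs in both it was 0.20 (-0.13 to 1.01). Over the full set the members thus did not move by equal amounts in the 2 classes. Members are not independent and the smaller set took in 0, so such handling is not excluded. In neuron-like cells the stricter filter left the median at -0.35, with a median change per member of 0.0149 (-0.0020 to 0.0359) where 0.18 was needed. This argues only against damaged cells over the stricter mitochondrial limit as the whole cause. Such cells were 77 of 2385 control and 380 of 2969 dHet neuron-like cells. Median mitochondrial shares only went from 4.49% (control) and 5.90% (dHet) to 4.46% and 5.64%. Most of that gap remained, so the filter cannot decide on damage among the cells it kept, which stays open. Handling that acted on the classes differently and the genotype stay open and were not tested.

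Gstp1 was higher and Tpm3-rs7 lower in the dHet library across classes. For Tpm3-rs7, reads shared with a near-identical copy stay open: Tpm3 and Tpm3-rs7 summed gave a ratio of 0.971 (0.949 to 0.994), but a fall of Tpm3-rs7 alone would have given 0.837, also inside the bounds of 1/1.2 and 1.2, so the test decides nothing. For Gstp1, UMIs moved between the counted copies are argued against, as the copies summed gave 2.59 (2.41 to 2.78). That sum was nearly all Gstp1, with 32 and 77 UMIs of Gstp2 and 0 of Gstp3 in both libraries. Shared reads that were counted for no copy would not appear in the sum, so the test cannot decide on them. A variant of the pooled animals stays open for Gstp1: it was lower in 0 of 7 classes with at least 50 UMIs, but this was already known and decides nothing. No biological explanation was tested.

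A further hypothesis was that Txnip in astrocyte-like cells and Zbtb16 and Cdkn1a in Agrp/Npy-like cells were higher through a glucocorticoid or fasting response in the dHet pool, since all 3 genes can be induced by glucocorticoids or fasting. The other glucocorticoid-induced genes had a median log2 ratio of 0.27 (-0.16 to 0.65) in astrocyte-like cells, with 12 of 16 higher, and of 0.12 (-0.27 to 0.30) in Agrp/Npy-like cells, with 8 of 12 higher. These medians lay at percentiles 99.99 and 97.36 of random lists, the latter just short of the bound set beforehand for both classes, and both intervals took in 0, so the test left the hypothesis open. The same list had medians of -0.17 in tanycyte-like cells (9 of 15 lower, percentile 0.94), -0.02 in neuron-like cells and -0.12 in Pomc-like cells. In Agrp/Npy-like cells Fkbp5 was higher (1.76) while Tsc22d3 was lower (0.690). Members also went both ways in astrocyte-like cells. Hif3a (5.77, 3.13 to 11.7) and Sult1a1 (4.85, 2.52 to 10.2) were higher there, while Nfkbia (0.726) and Bcl6 (0.560) were lower. Tanycyte-like cells had more Fkbp5 (2.84, 1.77 to 4.64) and less Cebpd (0.537, 0.463 to 0.621).

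Lower Dbp in Agrp/Npy-like cells raised the hypothesis that the 2 pools were collected at different times of day. With clock genes signed by their known phase relative to Dbp, 9 of 11 measured genes in these cells went the predicted way, with a signed median of 0.29 (-0.09 to 0.41), which did not decide it. In all neuron-like cells 5 of 12 did, with a signed median of 0.00. Dbp itself was higher in astrocyte-like cells (1.25, 1.06 to 1.47), and the labels give no collection time.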
